A study of Mus musculus with 19 samples.

How the data were processed

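The series measured single-cell transcriptomes of the lumbar spinal cord of adult male mice 14 days after spared nerve injury (SNI), in which branches of the sciatic nerve are cut and another is left intact, or after a superficial injury (SI), taken here as the surgical control. The labels gave 10 SI mice and 9 SNI mice, each 1 Drop-seq sample, and per the series text 1 further SNI mouse was removed by the submitters because it held transcripts of the dorsal root ganglion (DRG). In Drop-seq, single cells share droplets with beads whose oligonucleotides carry a cell barcode and a unique molecular identifier (UMI), so that each UMI counts 1 captured transcript. Per the labels' protocols, the tissue was digested with collagenase and a bacterial protease, cells were separated from debris on a Percoll gradient, and methanol-fixed cells were stored frozen before capture. The labels placed 5 SI and 3 SNI mice in cohort 1 and 5 SI and 6 SNI mice in cohort 2, each with 3 Drop-seq days, whereas the series text gave equal numbers of each injury per cohort and 4 Drop-seq days.

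The deposited raw table held UMI counts per gene and cell, which the authors had not normalized. Per the submitters' processing notes, reads were aligned with STAR to mm10 and hg19, and per the labels human embryonic kidney cells were used as spike-ins. The version of STAR was not given in the sources used here. The table held 21798 genes and 18856 cells. The counts of a cell summed to the total in the authors' deposited cell table in 18856 of them. The shallowest cell held 482 UMIs, and the fewest genes in a cell was 401. Another deposited table held a score for 14700 genes, which the authors had corrected for batch and scaled. In 147 of 147 sampled genes, cells without a UMI took exactly 6 values at 6 decimals, 1 for each labelled combination of cohort and day. The means of these genes lay between -0.00732 and 0.00704 and their median SD was 0.999. The scores served only for this check. The authors' cell table assigned cells to 66 subtypes by settings not given in the sources used here, and leaving off the number at the end of each name gave 18 cell types. Names are printed as deposited. Micro is read here as microglia, Macro as macrophages, Excit and Inhib as excitatory and inhibitory neurons, OPC as oligodendrocyte precursor cells, and Oligo and mylOligo as oligodendrocytes.

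Cells were not treated as replicates. Raw counts were summed per mouse and cell type, with its subtypes pooled and no term for their make-up. A mouse entered with at least 10 cells of the type, and a type was tested with at least 5 such mice per group, which left 9 types, and all cells summed gave a further fit. The sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization, a robust fit, and cohort, Drop-seq day and injury as terms. Genes were filtered by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15. P-values were adjusted by Benjamini and Hochberg's method within each fit, with a threshold of 0.05. Fold changes are SNI minus SI on the log2 scale. Levels are CPM, counts scaled to a common total over the tested genes with TMM factors. Values within a cohort are plain differences of group means of log2 CPM (prior count 2). Intervals cover 95%. The 24 gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with the same terms, a preset correlation between genes of 0.01 and at least 5 tested members, adjusted over all 48 tests of a list in a cell type. A further 18 combinations could not be tested. List medians come from that fit of log2 CPM, and counts of members higher or lower come from the edgeR fit, so that they can differ in sign near 0. Camera with an estimated correlation and fry, a rotation test, were alternatives.

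Shares, cells per mouse, depth and the UMIs of 20 marker classes were compared by a two-sided exact permutation test of the difference in means that moved injury labels only within combinations of cohort and day. It had 2240 assignments and a smallest possible p of 0.000446. The difference is that of plain group means, not adjusted for the unequal numbers of SNI mice per cohort. Intervals of these differences hold the shifts that the test did not reject. The difference in injury effect between cell types was tested for the named genes in edgeR, with mouse as a block and terms for cell type and cell type by cohort. Designs, gene lists, marker classes, alternatives except where stated, and the rule for naming genes were fixed before the data were examined. By that rule a fit named up to 10 higher and 10 lower genes among those that passed with the same sign in both cohorts, or the 2 genes with the smallest p where none passed. For each list in a cell type the 3 tested members with the smallest p were named. Fixed genes were P2ry12, Tmem119, Cx3cr1, Csf1r, Itgam, Cd68, Aif1, Apoe and Trem2 in microglia, Gfap and Serpina3n in astrocytes, Mbp in oligodendrocytes and Atf3 in neurons. Xist, Y-linked genes and models without a symbol were not named.

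Alternatives for the gene tests were DESeq2 1.42.0, size factors in place of TMM, no filter on low counts, no covariates, cohort alone, cohort and day set by sample number, the replicate number as a block, limma voom with quality weights, removal of doublets, at least 30 cells per mouse, and leaving out each mouse in turn. For shares they were no strata, logit shares in limma, strata by sample number, the block, doublet removal and leaving Oligo out of the denominator. Counting cells of a mouse whose barcodes differed only at base 10 as 1 cell was added later. Doublets were called per mouse with Scrublet (scanpy 1.11.5), which marked 271 of 18856 cells (1.44%). They were kept in the results unless stated. Gene positions and transcript lengths are from GENCODE vM21 on GRCm38, the assembly of mm10, where 145 of 146 named genes were placed. No pair of mice within a group agreed within sampling noise: over genes with at least 20 counts in a pair, chi-square per degree of freedom was at least 2.11 (median 5.43) in 81 pairs.

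The tests were tried on simulated counts drawn from the means of these mice with 200 genes changed per fit. Of 2-fold changes, 77.2% (Inhib, 6004 genes) to 94.4% (mylSchwann, 441 genes) were recovered, except in Leptomeningeal with 45.1% of 818 genes run. Of 4-fold changes, 98.0% were recovered in Leptomeningeal and 100.0% in each other fit. False calls made up 0% to 5.79% of calls. With 200 genes changed per fit, the adjusted threshold accepts larger p-values than where few genes change. These rates can thus overstate recovery of a few changed genes, most in the fits with few genes. Of 8 lists raised by 20%, 7 were recovered, and 0 unchanged lists were called. Genes were drawn independently here, so this could not show false calls from members that vary together. In these mice the estimated correlation reached 0.728 for oxidative phosphorylation in Oligo. The test between cell types recovered 69.7% of 2-fold and 96.6% of 4-fold differences in Endothelial against Oligo (4150 genes). For shares, the exact permutation test gave p under 0.05 for a simulated 2-fold change in 98.5% of 200 runs for Micro and 72.0% for Macro, for a 1.5-fold change in 70.0% and 26.0%, and with no change in 5.50% and 8.00%.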

Results

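Lumbar spinal cord cells were profiled by Drop-seq 14 days after spared nerve injury, a model of neuropathic pain, in 9 mice and after superficial injury in 10 mice. The 18856 annotated cells held 31506641 UMIs. Totals were 1858974, 3056935, 1105622, 2372215, 1334701, 1210644, 3069071, 913333, 944646 and 1458687 UMIs in SI mice 1 to 10, and 1213972, 1685180, 1948973, 2506268, 2292607, 901678, 1719573, 1631565 and 281997 UMIs in SNI mice 1, 2, 3 and 5 to 10. Mice yielded from 160 cells (SNI mouse 10) to 1830 cells (SI mouse 7), and the median UMIs per cell of a mouse lay between 969.5 and 1649. SI mice gave 1022 ± 530.5 cells (SD, n = 10) and SNI mice 959 ± 471 cells (SD, n = 9; difference -63.5, 95% interval -481 to 376, exact permutation p = 0.751). The difference was -354 cells in cohort 1 and 153 in cohort 2. Median depth was 1276 ± 202 UMIs per cell in SI and 1247 ± 202 in SNI mice (difference -29.9, 95% interval -231 to 161, exact permutation p = 0.740), with differences of 169 in cohort 1 and -137 in cohort 2. Cells and depth thus differed by less than the spread between mice.

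The first comparison asked whether the make-up of the recovered cells differed after nerve injury. Shares are of the annotated cells left after digestion, the gradient, fixation and capture, and need not equal those in the cord. Among these cells oligodendrocytes, the myelinating cells, were the most frequent, with Oligo at 33.1% ± 5.31 of SI and 34.0% ± 5.54 of SNI cells (SD, n = 10 and 9). Microglia, the resident macrophage-like cells of the cord, made up 3.91% ± 1.29 of SI and 4.08% ± 0.896 of SNI cells (difference 0.169 percentage points, 95% interval -0.965 to 1.08, exact permutation p = 0.726). Macrophages (Macro) averaged 1.42% ± 0.566 of SI and 0.758% ± 0.461 of SNI cells (SD, n = 10 and 9), and lay below the SI median in 8 of 9 SNI mice. Pericytes, contractile cells of capillary walls, averaged 1.85% ± 1.01 of SI and 0.993% ± 0.508 of SNI cells, below the SI median in 6 of 9 SNI mice. MylOligo averaged 15.6% ± 3.62 of SI and 19.4% ± 3.65 of SNI cells, above the SI median in 7 of 9 SNI mice.

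None of the 18 cell types passed after adjustment in the exact permutation test (0 at an adjusted p under 0.05, 3 at an unadjusted p under 0.05, and 0 by limma on logit shares). The difference in Macro was -0.660 percentage points (95% interval -1.26 to -0.169, exact permutation p = 0.0112, adjusted p = 0.201), with -0.603 in cohort 1 and -0.580 in cohort 2. The pooled value, not adjusted for cohort, lay beyond both. Pericyte differed by -0.858 percentage points (95% interval -1.80 to -0.0796, exact permutation p = 0.0241, adjusted p = 0.217), with -0.219 in cohort 1 and -1.30 in cohort 2. MylOligo differed by 3.77 percentage points (95% interval 0.130 to 7.37, exact permutation p = 0.0437, adjusted p = 0.263), with 0.751 in cohort 1 and 5.96 in cohort 2. Excit and Inhib differed by -0.0490 and 0.854 percentage points (exact permutation p = 0.966 and 0.374), and OPC by -0.643 (exact permutation p = 0.0683, adjusted p = 0.307). With cohort and day set by sample number, the Macro difference passed (exact permutation test, adjusted p = 0.0450). That setting puts SNI mouse 5 in cohort 1, which is nearer the equal numbers per cohort of the series text. It also moves SNI mice 6 and 7 to other days. In the authors' batch-corrected scores, cells without a UMI took 1 value for each labelled combination of cohort and day. The authors' correction thus went by the labelled assignment, under which Macro did not pass. Why the series text differs from the labels was not settled.

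**Figure D1:**
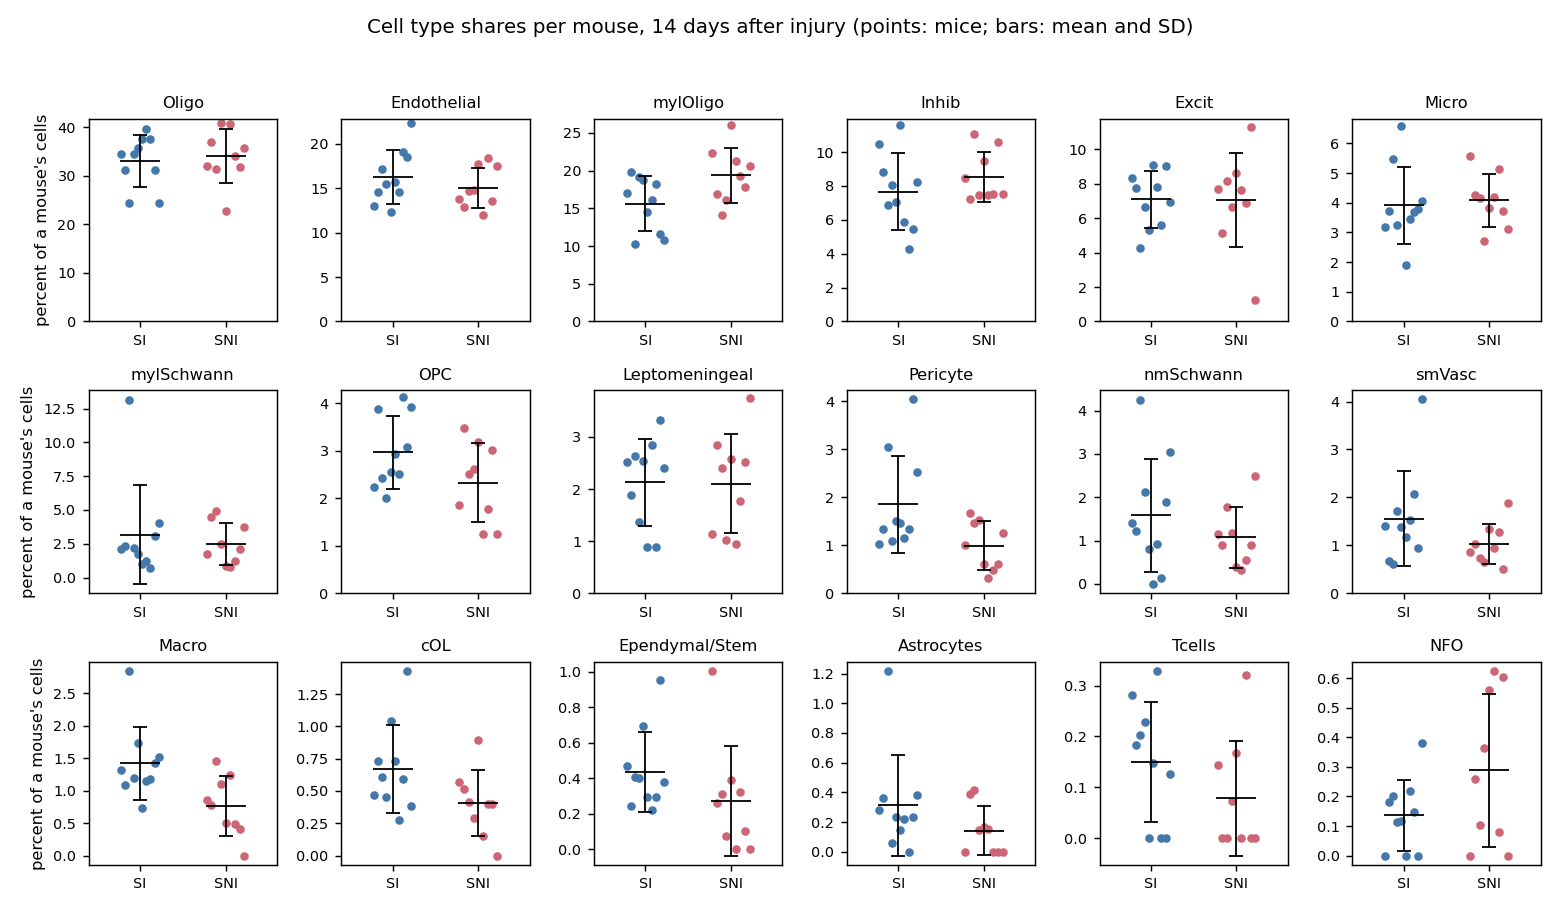
Percent of each mouse's cells (vertical axis) in each of the 18 cell types for SI (blue, n = 10) and SNI (red, n = 9) mice, with 1 point per mouse and bars for the mean and SD. Macro averaged 1.42% in SI and 0.758% in SNI mice, and Micro 3.91% and 4.08%.

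The next comparison asked which transcripts differed within each cell type, and over all annotated cells summed. Sema7a in Endothelial had the smallest p of any gene in the 10 fits. It encodes a membrane-anchored semaphorin (GRCm38 chromosome 9, 57940112 to 57962865), and stood at 225 ± 42.1 CPM in SI and 137 ± 15.2 CPM in SNI mice (SD, n = 10 and 9). It was below the SI median in 9 of 9 SNI mice (log2 difference -0.71, SE 0.15; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0634). Over all cells summed, Tenc1 (current symbol Tns2), a tensin of focal adhesions (chromosome 15, 102100413 to 102116401), stood at 62.1 ± 18.8 CPM in SI and 36.7 ± 10.6 CPM in SNI mice (SD, n = 10 and 9). It was below the SI median in 9 of 9 SNI mice (log2 difference -0.67, SE 0.14). Tbc1d22b, a gene with a TBC domain, had a log2 difference of -0.82 (SE 0.18), and was below the SI median in 9 of 9 SNI mice. Neither passed (same test, adjusted p = 0.413 for both). The differences were -0.63 in cohort 1 and -0.72 in cohort 2 for Sema7a and -0.78 in cohort 1 and -0.75 in cohort 2 for Tenc1. For genes named, here and below, for a small p in these mice, counts of mice beyond the SI median add no independent support.

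By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes passed in each of the 10 fits. At an unadjusted p under 0.05 there were 957 of 12393 genes in all cells summed, against 619.6 expected by chance. Such genes numbered 392 of 5704 in Endothelial (285 expected), 246 of 3454 in Excit (173 expected), 388 of 6258 in Inhib (313 expected), 32 of 865 in Leptomeningeal (43.2 expected) and 67 of 1045 in Micro (52.2 expected). They numbered 50 of 669 in OPC (33.5 expected), 492 of 6328 in Oligo (316 expected), 522 of 6264 in mylOligo (313 expected) and 23 of 480 in mylSchwann (24.0 expected). DESeq2 called 1 gene, Sema7a in Endothelial, and 0 in each other fit, and limma voom called 0 in all 10 fits. UMIs per mouse ranged from 11646 to 78718 in mylSchwann and from 99879 to 1004647 in Oligo.

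In microglia of SNI mice, genes of the disease-associated state, in which microglia take up lipid and debris, were higher as a list, and genes of the homeostatic state were lower. Both calls were lost when the correlation between genes was estimated (limma's camera, adjusted p = 0.545 and 0.574 with an estimated correlation), and the homeostatic median lay above 0 in cohort 2. The largest single difference among the genes with the smallest p was in Blnk, an adaptor of B cell receptor signalling (GRCm38 chromosome 19, 40928927 to 40994535), at 494 ± 189 CPM in SI and 225 ± 63.1 CPM in SNI mice (SD, n = 10 and 8). It was below the SI median in 8 of 8 SNI mice (log2 difference -1.10, SE 0.27; -0.75 in cohort 1 and -1.03 in cohort 2), and did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0959). Slc25a3, the mitochondrial phosphate carrier, stood at 359 ± 135 CPM in SI and 608 ± 191 CPM in SNI mice (SD, n = 10 and 8). It was above the SI median in 8 of 8 SNI mice (log2 difference 0.84, SE 0.24, adjusted p = 0.361 by the same test).

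Of the disease-associated list, 12 of 13 tested members were higher. The list median was a log2 difference of 0.24 (0.11 in cohort 1 and 0.21 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.545 with an estimated correlation). Its members with the smallest p were the ferritin heavy chain Fth1 (log2 difference 0.32, SE 0.12), the signalling adaptor Tyrobp (0.28, SE 0.13) and the lysosomal protease Ctsl (0.28, SE 0.17). Of the list 0 members passed over all genes or adjusted over the list alone (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.756 to 0.786 over all genes). Fth1 was above the SI median in 7 of 8 SNI mice. Of the homeostatic list, 13 of 16 tested members were lower. They had a median log2 difference of -0.10 (-0.23 in cohort 1 and 0.043 in cohort 2; limma's camera, adjusted p = 0.0365, and adjusted p = 0.574 with an estimated correlation). It was led by the fructose transporter Slc2a5 (log2 difference -0.57, SE 0.26), Olfml3 (-0.37, SE 0.20) and the purinergic receptor P2ry13 (-0.29, SE 0.22). Here too 0 members passed over all genes or adjusted over the list alone (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.756 to 0.845). The disease-associated call was lost without SI mouse 1 or 7 or SNI mouse 3 (limma's camera, adjusted p = 0.0683 to 0.278; medians without each mouse 0.16 to 0.30). The homeostatic call was lost without SI mouse 1, 3 or 8 or SNI mouse 1, 3, 6 or 9 (limma's camera, adjusted p = 0.0626 to 0.350; medians without each mouse -0.18 to -0.040). Micro pooled 3 subtypes, of which Micro3 made up 1.12% of SI and 0.645% of SNI cells (exact permutation p = 0.0121, adjusted p = 0.250). Micro1 made up 1.55% and 1.86%, and Micro2 1.24% and 1.57%. Whether the list differences came from this make-up was not tested. Macrophages share many of these genes, and UMIs of macrophage markers over all cells were 80.9 ± 48.8 CPM of all UMIs in SI and 45.8 ± 27.9 in SNI mice (exact permutation p = 0.0567, adjusted p = 0.283).

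The microglial genes fixed in advance did not pass. The purinergic receptor P2ry12 stood at 2850.3 ± 532 CPM in SI and 2516 ± 539 CPM in SNI mice (SD, n = 10 and 8; log2 difference -0.17, SE 0.15). Tmem119 differed by -0.21 (SE 0.16) and the fractalkine receptor Cx3cr1 by -0.087 (SE 0.13). The colony-stimulating factor 1 receptor Csf1r differed by -0.070 (SE 0.14), the integrin Itgam by -0.020 (SE 0.18), and the calcium-binding protein gene Aif1 by 0.11 (SE 0.16). The lysosomal gene Cd68 differed by 0.31 (SE 0.21), the lipid-sensing receptor Trem2 by 0.16 (SE 0.14) and the apolipoprotein gene Apoe by 0.85 (SE 0.65), with Apoe above the SI median in 5 of 8 SNI mice. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their adjusted p lay between 0.809 and 0.983. The sign for Itgam, Cx3cr1 and Csf1r turned to positive with no filter on low counts. Lists of antigen presentation, chemokines and cytokines, complement and microglial nerve injury genes had median log2 differences of 0.15, 0.15, 0.11 and 0.090 and were not called (limma's camera, adjusted p = 0.205, 0.368, 0.830 and 0.197). B2m, the light chain of MHC class I (log2 difference 0.35, SE 0.12), was the 1 gene of these lists that passed adjusted over the list alone, against 0 over all genes.

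**Figure D2:**
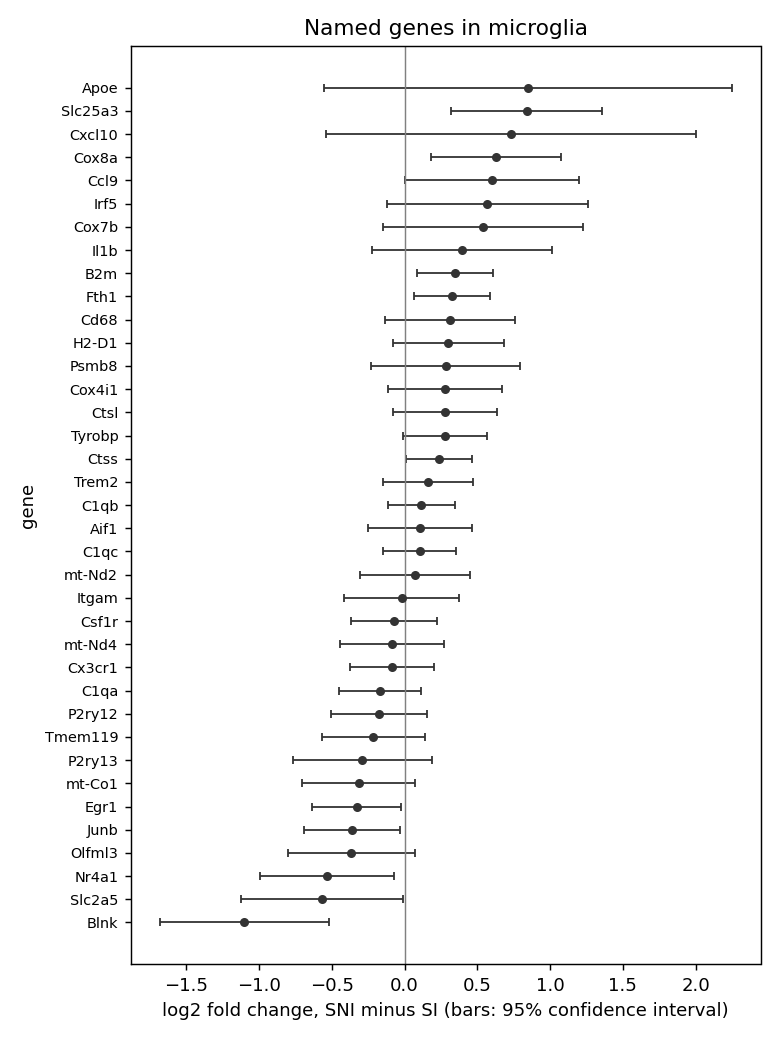
Log2 fold change, SNI minus SI (horizontal axis), of the named genes in microglia, with points for the estimate and bars for the 95% confidence interval over 10 SI and 8 SNI mice. Blnk lies lowest at -1.10 and Apoe highest at 0.85, and no gene passed.

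In neurons of SNI mice, oxidative phosphorylation genes, which encode subunits of the respiratory chain and ATP synthase, were higher as a list in Excit, genes of immediate early and handling responses were lower there, and genes of excitatory transmission were lower in Inhib. None of these 3 calls held in limma's camera when the correlation was estimated (adjusted p = 0.616, 0.545 and 0.545 with an estimated correlation). In Excit, 26 of 27 oxidative phosphorylation genes were higher, among them Cox7b (log2 difference 0.39, SE 0.15). Ndufa4 stood at 1829 ± 549 CPM in SI and 2411 ± 204 CPM in SNI mice (SD, n = 10 and 8; log2 difference 0.38, SE 0.14). The list had a median log2 difference of 0.25 (0.53 in cohort 1 and 0.14 in cohort 2; limma's camera, adjusted p = 0.000125, and adjusted p = 0.616 with an estimated correlation). Of its members 0 passed over all genes or adjusted over the list alone. Without SI mouse 1 the median was 0.12 and the list was not called (limma's camera, adjusted p = 0.0978). In Inhib 19 of 27 were higher (median 0.076, limma's camera, adjusted p = 0.0699). The list passed there in 8 alternative settings, and its median turned to -0.037 without SI mouse 1.

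Of the immediate early and handling list in Excit, 8 of 9 tested members were lower. Their median log2 difference was -0.29 (-0.0072 in cohort 1 and -0.47 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.545 with an estimated correlation). Members with the smallest p were the chaperone Hspa8 (log2 difference -0.36, SE 0.14), the transcription factor Klf6 (-0.49, SE 0.29) and Jund (-0.27, SE 0.22). In cohort 1 the median was near 0. The call was lost without SI mouse 8 or 10 or SNI mouse 3 or 8 (limma's camera, adjusted p = 0.0545 to 0.0916; medians without each mouse -0.37 to -0.19). Of the excitatory transmission list in Inhib, 12 of 13 tested members were lower. The list median was a log2 difference of -0.19 (-0.30 in cohort 1 and -0.20 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.545 with an estimated correlation). The list had a median length of 5713 nt against 3471 nt over all genes tested there, and its median lay at percentile 11.8 of random lists matched on length. The NMDA receptor subunit Grin1 stood at 372 ± 77.9 CPM in SI and 287 ± 65.5 CPM in SNI mice (SD, n = 10 and 9; log2 difference -0.39, SE 0.14). The calcium channel Cacna1b differed by -0.54 (SE 0.23) and the kinase Camk2a by -0.37 (SE 0.19). The call was lost without SI mouse 1 or 8 or SNI mouse 1 or 3 (limma's camera, adjusted p = 0.0591 to 0.124; medians without each mouse -0.27 to -0.13). Of these lists 0 members passed over all genes or adjusted over the list alone (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.739 to 0.770 over all genes for the members named in Inhib).

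Inhibitory transmission was lower in 10 of 13 members in Inhib and was not called (median -0.17, limma's camera, adjusted p = 0.0636). Gad1, which makes GABA, stood at 939.9 ± 284 CPM in SI and 717 ± 99.1 CPM in SNI mice (SD, n = 10 and 9; log2 difference -0.38, SE 0.14). The glycine transporter Slc6a5 differed by -0.44 (SE 0.19; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.739 for Gad1 and 0.761 for Slc6a5). The growth cone gene Gap43 stood at 684 ± 83.9 CPM in SI and 896 ± 149 CPM in SNI mice (SD, n = 10 and 9) in Inhib. It was above the SI median in 9 of 9 SNI mice (log2 difference 0.39, SE 0.12; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.732). It was the 1 member of the axon injury list that passed adjusted over the list alone, against 0 over all genes. Among dorsal horn peptides, somatostatin (Sst) differed by 1.05 (SE 0.51), dynorphin (Pdyn) by -0.83 (SE 0.41) in Inhib and neurotensin (Nts) by 0.88 (SE 0.36) in Excit, and none passed. Excit and Inhib pooled subtypes, and the shares of Inhib6 and Inhib8 are given among the other observations. Whether the differences in neurons came from this make-up was not tested. Magoh in Inhib (log2 difference 0.89, SE 0.20), a part of the exon junction complex, and Epb4.1l4b in Excit (-0.91, SE 0.24) had the smallest p of their fits (adjusted p = 0.435 and 0.413 by the same test). Atf3, a transcription factor induced by axon injury, had 12 UMIs in SI and 9 in SNI mice in Excit and 15 and 11 in Inhib, too few to be tested.

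In the oligodendrocyte lineage, oxidative phosphorylation genes were higher as a list in Oligo and mylOligo, immediate early and handling genes were lower in Oligo, and identity genes were lower in OPC. None of these 4 calls held in limma's camera when the correlation was estimated (adjusted p = 0.781, 0.747, 0.545 and 0.545 with an estimated correlation). Myelin genes were not called. Hspa8, a constitutive chaperone of the handling list, had the smallest p of that list in both. In Oligo it stood at 628 ± 110.0 CPM in SI and 425 ± 161 CPM in SNI mice (SD, n = 10 and 9; log2 difference -0.56, SE 0.15), below the SI median in 8 of 9 SNI mice. In mylOligo it differed by -0.47 (SE 0.13; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.479 in Oligo and 0.411 in mylOligo). Cspg4, the proteoglycan that marks precursor cells, stood in OPC at 3627 ± 702 CPM in SI and 2459.6 ± 699 CPM in SNI mice (SD, n = 10 and 7). It was below the SI median in 7 of 7 SNI mice (log2 difference -0.51, SE 0.18; same test, adjusted p = 0.386).

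Of the oxidative phosphorylation list in Oligo, 21 of 27 tested members were higher. They had a median log2 difference of 0.11 (0.30 in cohort 1 and -0.0030 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.781 with an estimated correlation). In mylOligo 23 of 27 tested members were higher. Their median log2 difference was 0.12 (0.31 in cohort 1 and 0.035 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.747 with an estimated correlation). MylOligo pooled subtypes, and the share of mylOligo1 is given among the other observations. Whether the list difference came from this make-up was not tested. In Micro 16 of 21 tested members were higher. The list median was a log2 difference of 0.20 (0.18 in cohort 1 and 0.078 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.545 with an estimated correlation). Examples are Cox7a2 in Oligo (log2 difference 0.31, SE 0.14), Cox4i1 in mylOligo (0.25, SE 0.099) and Cox8a in Micro (0.63, SE 0.21). In each of the 3 types 0 members passed over all genes or adjusted over the list alone (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.592, 0.542 and 0.658 over all genes). The Oligo call was lost without SI mouse 1 or 7 or SNI mouse 1 or 3 (limma's camera, adjusted p = 0.0642 to 0.860; medians without each mouse 0.016 to 0.19). The mylOligo call was lost without SI mouse 1 or 7 or SNI mouse 1 (limma's camera, adjusted p = 0.0573 to 0.788; medians without each mouse 0.046 to 0.20), and the Micro call without SI mouse 1 or 8 or SNI mouse 1 or 3 (limma's camera, adjusted p = 0.0591 to 0.186; medians without each mouse 0.14 to 0.34). Oxidative phosphorylation transcripts are short, with a median length of 857 nt in Excit against 3318 nt over all genes tested there. Mean log2 CPM of transcripts of at most 2226 nt minus that of transcripts of at least 4932 nt was 0.38 ± 0.31 in SI and 0.56 ± 0.15 in SNI mice (SD, n = 10 and 9; exact permutation p = 0.150). The difference was 0.34 in cohort 1 and 0.037 in cohort 2. Without SI mouse 1, a setting chosen after its value was seen, it was 0.18 in cohort 1, and over both cohorts 0.099 against 0.18 with all mice. In cohort 2 it ran from -0.014 to 0.098 without each mouse in turn.

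Of the immediate early and handling list in Oligo, 13 of 17 tested members were lower. They had a median log2 difference of -0.21 (0.0047 in cohort 1 and -0.31 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.545 with an estimated correlation). This call held without any 1 mouse. The 1 member that passed adjusted over the list alone, against 0 over all genes, was Hspa8. Junb, a subunit of the AP-1 transcription factor, had a log2 difference of -0.80 (SE 0.28). In mylOligo the same list was not called (median 0.042, limma's camera, adjusted p = 0.935), and there too Hspa8 was the 1 gene to pass adjusted over the list alone. Of the myelin list 11 of 16 were higher in Oligo and 11 of 16 in mylOligo (medians 0.027 and 0.041, limma's camera, adjusted p = 0.346 and 0.496). Mbp, the myelin basic protein gene, had a log2 difference of 0.080 (SE 0.10) in Oligo and 0.072 (SE 0.098) in mylOligo. Of the OPC identity list, 11 of 13 tested members were lower. Their median log2 difference was -0.23 (-0.35 in cohort 1 and -0.18 in cohort 2; limma's camera, adjusted p = 0.0297, and adjusted p = 0.545 with an estimated correlation). After Cspg4 came the matrilin Matn4 (log2 difference -0.61, SE 0.29) and the phosphatase receptor Ptprz1 (-0.37, SE 0.18). Of the list 0 members passed over all genes or adjusted over the list alone. OPC pooled subtypes, of which the share of OPC3 differed by -0.523 percentage points (0.228 in cohort 1 and -1.08 in cohort 2; exact permutation p = 0.0661, adjusted p = 0.436). The share of OPC2 differed by -0.286 and that of OPC1 by 0.167. Whether the list differences in OPC, here and below, came from this make-up was not tested. UMIs of OPC markers over all cells were 196 ± 44.3 CPM of all UMIs in SI and 142 ± 29.8 in SNI mice (exact permutation p = 0.00357, adjusted p = 0.0714). That class holds Cspg4 and Matn4 of the same mice, so it gives the identity list no independent support. A total over all cells also varies with the share of OPC, given above, and Cspg4 is in the pericyte class too. Of the mitochondrial transcripts in OPC, 7 of 8 tested members were higher. The list median was a log2 difference of 0.22 (0.085 in cohort 1 and 0.33 in cohort 2; limma's camera, adjusted p = 0.0365, and adjusted p = 0.616 with an estimated correlation). The complex I subunit mt-Nd2 (log2 difference 0.53, SE 0.17) was the 1 gene to pass adjusted over the list alone, against 0 over all genes. The identity call was lost without SI mouse 1, 7 or 8 or SNI mouse 1, 3, 5 or 6 (limma's camera, adjusted p = 0.0553 to 0.176; medians without each mouse -0.29 to -0.13). The mitochondrial call was lost without SI mouse 5, 6, 7 or 8 or SNI mouse 1, 3, 6 or 9 (limma's camera, adjusted p = 0.0679 to 0.247; medians without each mouse 0.12 to 0.28).

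**Figure D3:**
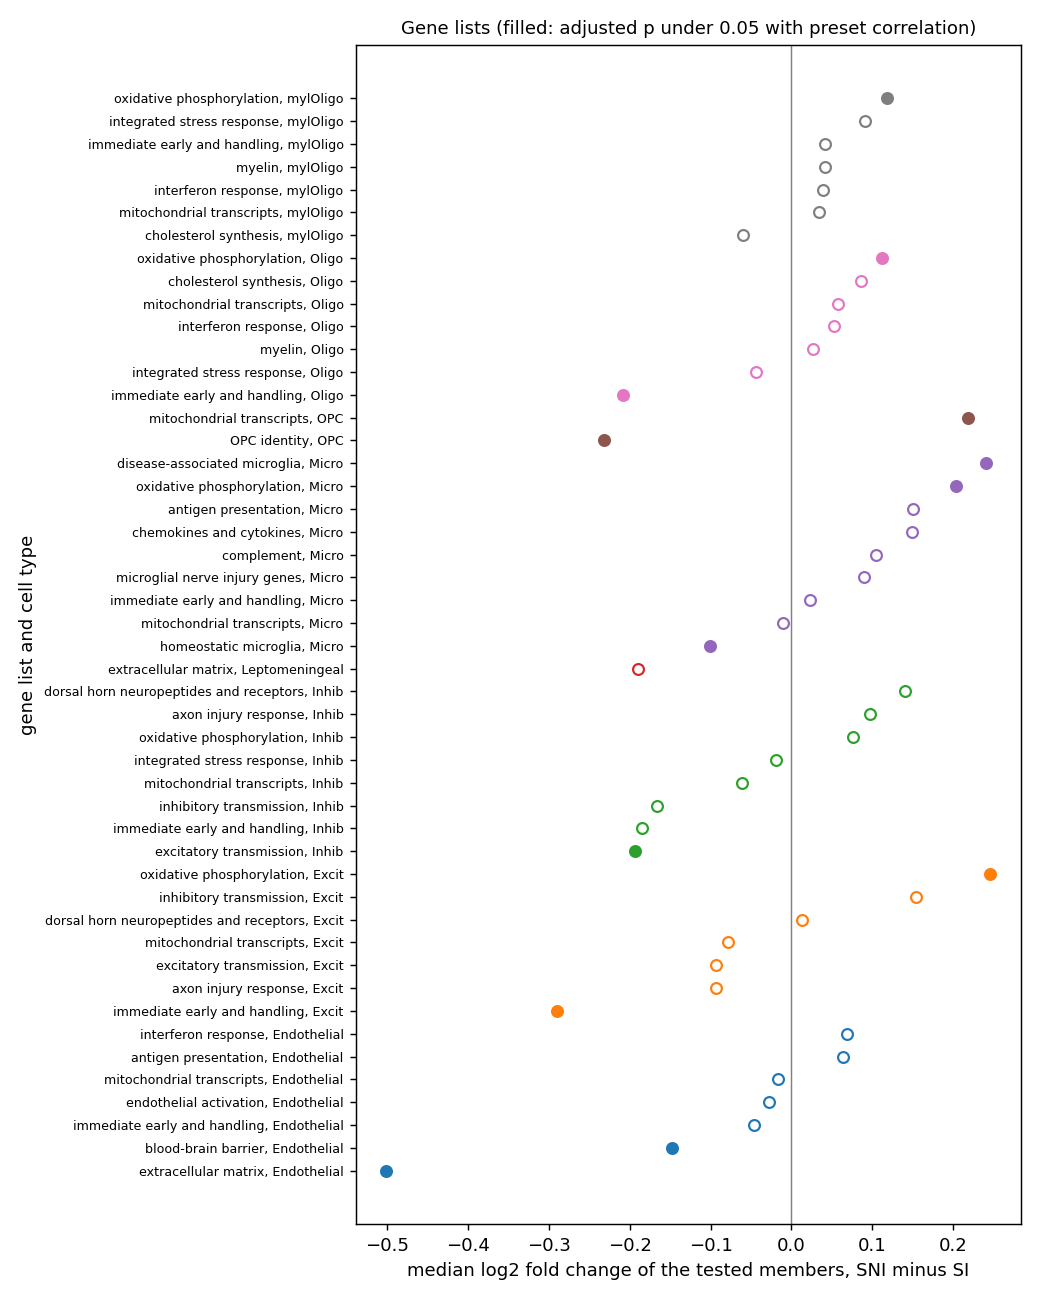
Median log2 fold change, SNI minus SI (horizontal axis), of the tested members of each gene list in each cell type (vertical axis, coloured by cell type), with filled points for the 13 tests called with the preset correlation and open points for the others. Extracellular matrix in Endothelial is lowest at -0.50 and oxidative phosphorylation in Excit highest at 0.25.

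In Endothelial of SNI mice, genes of the blood-brain barrier and of the extracellular matrix were lower as lists. Both calls were lost in limma's camera when the correlation was estimated (adjusted p = 0.545 and 0.545 with an estimated correlation), and fry called neither. Slc7a5, the large neutral amino acid transporter of the barrier, stood at 530.0 ± 125 CPM in SI and 393 ± 146 CPM in SNI mice (SD, n = 10 and 9; log2 difference -0.51, SE 0.15, below the SI median in 8 of 9 SNI mice). The glucose transporter Slc2a1 stood at 3474 ± 939 CPM in SI and 2716 ± 639.8 CPM in SNI mice (SD, n = 10 and 9; log2 difference -0.32, SE 0.13). The efflux pump Abcb1a differed by -0.28 (SE 0.13; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.525 to 0.700 for the 3). Among matrix genes, the collagen genes Col1a2 and Col4a2 differed by -1.14 (SE 0.39) and -0.42 (SE 0.17), and the laminin gene Lamc1 by -0.82 (SE 0.30; same test, adjusted p = 0.563 to 0.595).

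Of the barrier list, 15 of 15 tested members were lower. They had a median log2 difference of -0.15 (-0.33 in cohort 1 and -0.069 in cohort 2; limma's camera, adjusted p = 0.0197, and adjusted p = 0.545 with an estimated correlation). The list had a median length of 3441 nt against 3267 nt over all genes tested there, and its median lay at percentile 8.39 of random lists matched on length. Slc7a5 was the 1 member that passed adjusted over the list alone, against 0 over all genes. Of the matrix list, 7 of 8 tested members were lower. Their median log2 difference was -0.50 (-0.56 in cohort 1 and -0.30 in cohort 2; limma's camera, adjusted p = 0.0345, and adjusted p = 0.545 with an estimated correlation). Col1a2, Lamc1 and Col4a2 were the 3 members that passed adjusted over the list alone, against 0 over all genes. Col1a2 is made by fibroblasts, whose markers over all cells were 854 ± 359 CPM of all UMIs in SI and 864 ± 417 in SNI mice (exact permutation p = 0.948, adjusted p = 0.948). Pericytes and smooth muscle cells also make basement membrane genes such as Col4a2 and Lamc1. Pericyte markers were 791 ± 296 CPM of all UMIs in SI and 554 ± 187 in SNI mice (exact permutation p = 0.0567, adjusted p = 0.283), and smooth muscle markers 614 ± 381 CPM of all UMIs in SI and 436 ± 119 in SNI mice (exact permutation p = 0.129, adjusted p = 0.518). The share of Pericyte is given above. The barrier call was lost without SI mouse 1 or 8 or SNI mouse 1, 3 or 6 (limma's camera, adjusted p = 0.0530 to 0.179; medians without each mouse -0.21 to -0.062). The matrix call was lost without SI mouse 1, 2, 5, 7 or 10 or SNI mouse 1, 2, 3 or 6 (limma's camera, adjusted p = 0.0507 to 0.0961; medians without each mouse -0.60 to -0.29). In antigen presentation, which was not called (limma's camera, adjusted p = 0.197), B2m (log2 difference 0.36, SE 0.12) and the immunoproteasome gene Psmb8 (0.39, SE 0.14) were the 2 members that passed adjusted over the list alone, against 0 over all genes. In Leptomeningeal, Tsc22d3, a gene induced by glucocorticoids, differed by -0.996 (SE 0.29; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.997).

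Over all 48 tests of a list in a cell type, 13 were called with the preset correlation, 6 higher and 7 lower in SNI. With an estimated correlation, camera called 0 (smallest adjusted p = 0.545, 1 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, called 0 (smallest adjusted p = 0.313, 7 unadjusted). The median, mean and test of a list differed in sign in 7 tests that were not called. These were interferon response, endothelial activation, mitochondrial transcripts and immediate early and handling in Endothelial, axon injury response in Excit, mitochondrial transcripts in Inhib, and immediate early and handling in Micro. Astrocytes were rare among the annotated cells, with 27 cells in SI and 13 in SNI mice. They held 7 and 3 UMIs of the filament gene Gfap and 0 and 0 of Serpina3n, so that a difference was not detectable at this depth. Whether injury acted differently on a named gene in a pair of cell types was tested 1057 times, with 1 test passing and 137 at an unadjusted p under 0.05. Most of these genes were named for a small p in 1 of the cell types, so that the test was not independent of how they were chosen.

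Transcripts of DRG sensory neurons were high in SI mouse 4. A set of 7 genes, among them the filament gene Prph and the sodium channel genes Scn10a and Scn11a, was taken after their values were seen from the marker class of 11 fixed before, leaving out Calca, Nefh, Pou4f1 and Isl1. They gave 93.6 CPM of all UMIs in SI mouse 4, against 9.68 in the next mouse, SI mouse 1, and a median of 2.24 over the other mice. Over all 11 genes of the class, the values were 325 in SI mouse 4 and 178 in the next mouse, SNI mouse 9. Of the 1753 cells of SI mouse 4, 203 (11.6%) held a UMI of these genes, against 0.491% of cells of the other mice. The share was 8.60% in Oligo (95% Wilson interval 6.61 to 11.1, median depth 988 UMIs), which should lack them, and 13.7% in Excit (8.60 to 21.1, 1384 UMIs). Without SI mouse 4 the number of lists called was 13.

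**Figure D4:**
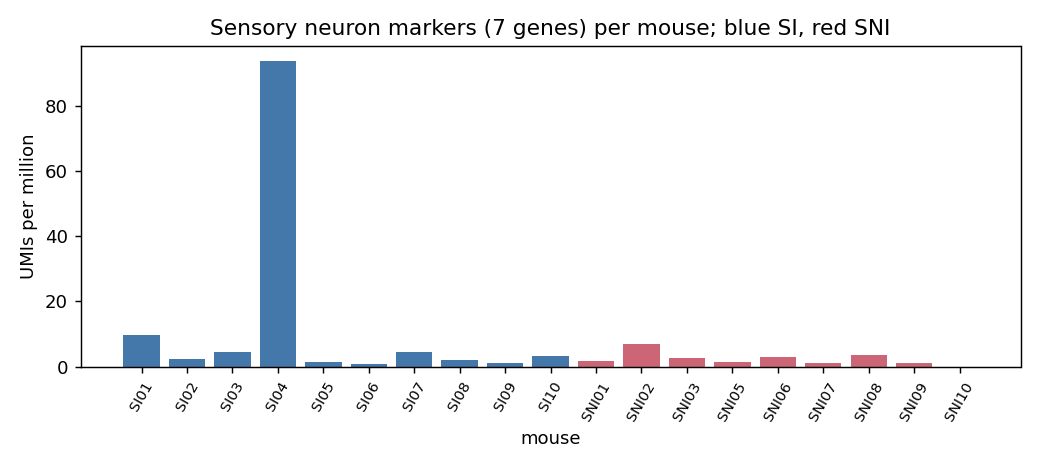
CPM of all UMIs (vertical axis) of 7 DRG sensory neuron genes in each SI (blue) and SNI (red) mouse (horizontal axis), with 1 bar per mouse. SI mouse 4 stands at 93.6 and the next, SI mouse 1, at 9.68.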

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

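The tests of transcript length, of sharing between cell types and of splits on oxidative phosphorylation genes and on gene lists were set before their results were seen. The test between cell types, camera with an estimated correlation and fry were also planned. All other tests below were chosen after. These include those without SI mouse 1, of excitatory neurons alone, of length over the called lists, of gene counts, of sensory transcripts, of marker classes and of barcodes. Single mice far from the others of their group by Dixon's rule stood out in 64 of 432 groups of values, where about 1 group in 20, or 21.6, would by chance. That rate assumes independent groups of normally distributed values. Many groups here hold genes of the same mice, and 13 of the 64 were for SI mouse 1. The excess is thus no count of separate events. The number after each item is the gap to the nearest mouse as a part of the whole range. Genes are on the log2 CPM scale.

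SI mouse 1 was lowest for short minus long transcripts (0.534), Atp5j in Oligo (0.531), C1qc in Micro (0.466), Cox4i1 in Oligo (0.538) and Cox4i1 in mylOligo (0.585). It was also lowest for Cox6b1 in mylOligo (0.486), Cox7a2 in Oligo (0.521), Cryab in mylOligo (0.547), Klf2 in Endothelial (0.485) and Mbp in Oligo (0.527). It was also lowest for Ndufa4 in Inhib (0.510), Ndufb11 in Inhib (0.685) and Ndufb11 in mylOligo (0.474). SI mouse 3 was lowest for Klf6 in Excit (0.640). SI mouse 3 was highest for the share of Astrocytes (0.687), the share of Macro (0.523), the share of mylSchwann (0.733), Schwann cell class (CPM of all UMIs) (0.773) and macrophage class (CPM of all UMIs) (0.511). SI mouse 4 was lowest for Nmu in Excit (0.492). SI mouse 4 was highest for sensory neuron markers (CPM of all UMIs) (0.905), DRG neuron class (CPM of all UMIs) (0.635) and neutrophil class (CPM of all UMIs) (0.964). SI mouse 5 was lowest for Bcr in mylOligo (0.519), Ddit3 in Inhib (0.523) and Trem2 in Micro (0.518). SI mouse 5 was highest for Slc6a5 in Inhib (0.641). SI mouse 6 was lowest for committed oligodendrocyte precursor class (CPM of all UMIs) (0.550), Lamc1 in Endothelial (0.630), P2ry13 in Micro (0.591), Slc7a5 in Endothelial (0.597) and Tap2 in Endothelial (0.480). SI mouse 7 was lowest for mt-Co1 in Excit (0.493). SI mouse 8 was highest for Irf5 in Micro (0.5001). SI mouse 9 was lowest for Cebpg in Oligo (0.506), Hspa8 in Excit (0.551), Ifi27l2a in mylOligo (0.609) and Lss in Oligo (0.711). SI mouse 9 was highest for ependymal class (CPM of all UMIs) (0.499). SI mouse 10 was highest for the share of smVasc (0.577) and smooth muscle class (CPM of all UMIs) (0.629).

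SNI mouse 1 was lowest for Aif1 in Micro (0.698), Atraid in Excit (0.593), Grin1 in Inhib (0.565), Prdx2 in OPC (0.755) and Trem2 in Micro (0.639). SNI mouse 1 was highest for the share of Ependymal/Stem (0.609). SNI mouse 2 was lowest for Fn1 in Leptomeningeal (0.654). SNI mouse 2 was highest for sensory neuron markers (CPM of all UMIs) (0.510). SNI mouse 3 was highest for astrocyte class (CPM of all UMIs) (0.596) and erythroid class (CPM of all UMIs) (0.817). SNI mouse 6 was lowest for Atf4 in Oligo (0.571). SNI mouse 6 was highest for Mbp in Oligo (0.523) and Mbp in mylOligo (0.525). SNI mouse 7 was lowest for mt-Co1 in Excit (0.528), mt-Co1 in mylOligo (0.495) and mt-Nd2 in Micro (0.668). SNI mouse 7 was highest for Cox7b in Micro (0.551). SNI mouse 8 was highest for neutrophil class (CPM of all UMIs) (0.896). SNI mouse 10 was lowest for Ier2 in Inhib (0.559), Slc3a2 in Inhib (0.808), Sst in Inhib (0.693), Tbc1d22b in all cells summed (0.538) and Vcam1 in Endothelial (0.581).

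A difference between cell types stood out for Prrc2c, whose injury effect was 1.51 log2 units higher in Leptomeningeal than in Endothelial over 14 mice, in the 1 of 1057 tests that passed (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0466). Prrc2c was in the test because it had 1 of the 2 smallest p in Leptomeningeal in the same mice, where it did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.997), so the test gives no independent support.

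Splits moved injury labels over all mice of a fit, not within cohort and day, and the 100 include the real one. Since the real split of the mice gave 0 genes past the threshold in every fit, the 100 of 100 splits with as many decide nothing. The highest other count was 25 genes, in Leptomeningeal, where 5 of 100 splits called any gene. For genes at an unadjusted p under 0.05, as many or more came in 9 of 100 in all cells summed (real 957, highest other 2186), 9 of 100 in Endothelial (real 392, highest other 716) and 11 of 100 in Excit (real 246, highest other 432). They came in 13 of 100 in Inhib (real 388, highest other 781), 59 of 100 in Leptomeningeal (real 32, highest other 115) and 12 of 100 in Micro (real 67, highest other 98). In the other fits they came in 2 of 100 in OPC (real 50, highest other 50), 6 of 100 in Oligo (real 492, highest other 736), 10 of 100 in mylOligo (real 522, highest other 834) and 31 of 100 in mylSchwann (real 23, highest other 40). In OPC alone the share of such splits was under 0.05.

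Among gene lists, 4 of 100 splits, the real one among them, called as many as the real 13 (highest other 15). Of the other splits 92 called at least 1 list, with a median of 5 lists called. The medians of 6 of the 13 called lists lay outside the central 95% of random lists matched on transcript length. Random lists lack the correlation between members of a real list, so this range can be too narrow. Called lists inside it were the barrier, excitatory transmission and homeostatic lists, mitochondrial transcripts in OPC, and oxidative phosphorylation in Micro, Oligo and mylOligo.

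The pattern a biologist would first follow up is oxidative phosphorylation, called higher in Excit, Micro, Oligo and mylOligo with the preset correlation, and in 0 types with an estimated correlation or by fry. In Excit, taken alone after the results were seen, the median stood at percentile 99.6 of 10000 length-matched lists. This cannot decide on length, since random lists lack the members' correlation (estimated at 0.569 in Excit) and so vary less. Of the called types, 1 of 4, or 1 of 4 matched on length and expression, passed the upper bound of the central 95% of matched lists. Transcript length stayed open in all 4. A difference between mice shared by their cell types stayed open, with a mean correlation of 0.843 over 10 pairs of types against 0.166 as the upper bound of the central 95% of shuffles. Without SI mouse 1, lowest in short against long transcripts, 0 tests of the list passed, and 30 of 100 splits called as many as the real 4 (highest other 5), so that a rise in respiration after injury was not shown.

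For the sensory neuron transcripts of SI mouse 4, intact sensory neurons among the annotated neurons were argued against, since Excit and Inhib held 19.4% of the marker UMIs (95% interval 14.7 to 25.1). RNA free in the suspension stayed open: neurons held 0.926 times the share of the other types (95% interval 0.665 to 1.29), and no cell held more than 3 marker UMIs. An exchange of labels with the SNI library that the submitters removed cannot be told apart, since SI mouse 4 gave 93.6 CPM of all UMIs and the removed library was not analysed here. No biological explanation was tested.

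Among barcodes of 1 mouse, 1215 pairs differed at 1 base, against 24.4 expected from pairs between mice, which argued against chance likeness, and 1146 pairs had A and G at base 10. Rare random sequencing errors were argued against, as the smaller cell held a median of 51.2% of its partner's UMIs. That value cannot decide on an error repeated at 1 base. Of pairs within mice 95.1% differed at base 10, against 7.10% of pairs between mice. 1 bead read as 2 cells stayed open: 75.1% of pairs shared a subtype (95% interval 72.6 to 77.4), against 11.6% of pairs between mice. Counting such pairs at base 10 once left 17703 cells. No biological explanation was tested.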

How the results depend on the processing

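Counting barcode pairs once, and leaving out each mouse for gene lists, were chosen after the data were seen. So were the length score without SI mouse 1 and the marker class means without single mice, given elsewhere. All other alternatives were set before. Of 4901 values of named genes under alternatives, 4877 kept direction and side of the threshold, 8 newly passed and 16 turned. For lists these were 923 of 1104, with 94 no longer passing, 21 newly passing and 66 turned, and for shares 439 of 467, with 1 newly passing and 27 turned. For cells and depth they were 36 of 44, with 8 turned. At the cells and depth of Leptomeningeal, 45.1% of simulated 2-fold changes were recovered. Where a value below turned or a count moved, the cause was not tested. At least 30 cells per mouse gave no value for Leptomeningeal, which had too few such mice, nor for all cells summed.

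The number of genes passing was 0 in all 10 fits (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). DESeq2 called 1 in Endothelial (Sema7a), and cohort alone 1 in Endothelial (Sema7a). With no filter on low counts edgeR called 4 in Endothelial (Fkbp5, S100a8, S100a9 and Sult1a1), 1 in Inhib (Dlk1) and 4 in Leptomeningeal (Hba-a1, Hba-a2, Hbb-bt and Ibsp). S100a8 and S100a9 are neutrophil transcripts, and neutrophil markers stood at 575 CPM of all UMIs in SNI mouse 8. Hba-a1, Hba-a2 and Hbb-bt are erythroid, and erythroid markers stood at 2109 in SNI mouse 3. The same setting called 2 in Micro (Cxcl2 and Il12b), 5 in Oligo (Arrdc2, C4b, Hspa8, Leng8 and Myrf) and 1 in mylSchwann (Spp1). At least 30 cells per mouse gave 2 in mylSchwann (Ly6a and Spp1). Without 1 mouse in turn, counts ran from 0 to 1 in Endothelial (Sema7a without SI mouse 9), 0 to 3 in Leptomeningeal (hemoglobin genes of erythroid cells, without SI mouse 1 or SNI mouse 5) and 0 to 1 in Micro (Blnk without SI mouse 2). They ran from 0 to 4 in mylOligo (Bcr, Leng8, Per3 and Tmem178b without SI mouse 6) and 0 to 1 in mylSchwann (Apod without SI mouse 7), and stayed at 0 in Excit, Inhib, OPC, Oligo and all cells summed.

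Of 48 list tests, 13 were called with the preset correlation of limma's camera, 0 with an estimated correlation and 0 by fry. Without 1 mouse in turn the number ran from 3 without SI mouse 1 to 16 without SI mouse 6. It was 3 without SNI mouse 3, 4 without SNI mouse 1, 7 without SI mouse 8, 8 without SI mouse 7 and 8 without SNI mouse 6. Lists that newly passed were inhibitory transmission in Inhib in 9 settings (medians -0.26 to -0.18, adjusted p = 0.0193 to 0.0444), all without 1 mouse, and oxidative phosphorylation in Inhib in 8 settings (medians 0.094 to 0.19, adjusted p = 0.00108 to 0.0444), with no covariates or without SI mouse 2, 5, 6 or 9 or SNI mouse 8, 9 or 10. Excitatory transmission in Excit (-0.20), microglial nerve injury genes in Micro (0.15) and chemokines and cytokines in Micro (0.37) passed without SI mouse 6, and cholesterol synthesis in Oligo (0.15) without SI mouse 8. With no covariates, list medians turned for immediate early and handling in Endothelial 0.037, mitochondrial transcripts in Oligo -0.018 and mitochondrial transcripts in mylOligo -0.027. Without 1 mouse in turn, medians of lists that turned ran over dorsal horn neuropeptides and receptors in Excit -0.12 to 0.16, endothelial activation in Endothelial -0.18 to 0.19, immediate early and handling in Endothelial -0.13 to 0.062, immediate early and handling in Micro -0.089 to 0.13 and immediate early and handling in mylOligo -0.023 to 0.10. Further ranges were integrated stress response in Inhib -0.052 to 0.036, interferon response in Endothelial -0.026 to 0.10, interferon response in Oligo -0.096 to 0.17, interferon response in mylOligo -0.10 to 0.25 and mitochondrial transcripts in Endothelial -0.069 to 0.054. Further ranges were mitochondrial transcripts in Inhib -0.073 to 0.054, mitochondrial transcripts in Micro -0.14 to 0.075, mitochondrial transcripts in Oligo -0.0086 to 0.11, mitochondrial transcripts in mylOligo -0.031 to 0.084 and oxidative phosphorylation in Inhib -0.037 to 0.19.

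Among named genes, no filter on low counts turned the log2 difference of Cx3cr1 in Micro 0.022, mt-Nd4 in Micro 0.020, Csf1r in Micro 0.036 and Itgam in Micro 0.090, doublet removal that of Itgam in Micro 0.021, and at least 30 cells that of mt-Nd1 in Endothelial -0.0035. Without 1 mouse in turn, genes that turned ran over Cx3cr1 in Micro -0.19 to 0.028, Ifi27l2a in mylOligo -0.27 to 0.75, Itgam in Micro -0.15 to 0.12, mt-Nd1 in Endothelial -0.0035 to 0.096, mt-Nd2 in Micro -0.012 to 0.14 and mt-Nd4 in Micro -0.21 to 0.031.

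The share of Macro passed with cohort and day by sample number (-0.660, exact permutation test, adjusted p = 0.0450). Barcode pairs counted once gave share of Excit 0.0687, and limma on logit shares share of Leptomeningeal 0.00987, share of mylSchwann 0.0469 and share of nmSchwann 0.0914. Without 1 mouse in turn, differences in percentage points ran over share of Astrocytes -0.206 to -0.0714, share of Endothelial -1.67 to -0.559, share of Ependymal/Stem -0.253 to -0.104, share of Excit -0.579 to 0.674, share of Inhib 0.477 to 1.29 and share of Leptomeningeal -0.230 to 0.122. Further ranges were share of Macro -0.748 to -0.503, share of Micro -0.0535 to 0.467, share of NFO 0.110 to 0.188, share of OPC -0.787 to -0.508, share of Oligo -0.0454 to 2.34 and share of Pericyte -0.949 to -0.615. Further ranges were share of Tcells -0.101 to -0.0514, share of cOL -0.326 to -0.181, share of mylOligo 2.93 to 4.43, share of mylSchwann -0.999 to 0.413, share of nmSchwann -0.686 to -0.211 and share of smVasc -0.638 to -0.253. Cells per mouse differed by -167 to 36.4 and median UMIs per cell by -73.2 to 11.5.

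The replicate numbers gave no sign of pairing: over 9 pairs of equal number, deviations from the group means correlated between -0.0508 and 0.0952, 0 over 0.1, and 0 mice correlated best with their own number. With the number as a replicate block, 5 lists were called, and genes passing were 2 in Leptomeningeal (Hba-a1 and Hba-a2), 1 in mylSchwann (Apod) and 0 in each other fit. The block turned immediate early and handling in Endothelial 0.052, mitochondrial transcripts in Oligo -0.014, mitochondrial transcripts in mylOligo -0.020 and the difference in cells per mouse (17.7).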

Other observations

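At the finer resolution of the authors' subtypes, mylOligo1 made up 5.03% ± 2.16 of SI and 8.97% ± 3.47 of SNI cells (4.29 in cohort 1 and 3.76 in cohort 2; exact permutation p = 0.0107, adjusted p = 0.250). Among macrophages, Macro2 made up 0.704% ± 0.419 of SI and 0.353% ± 0.195 of SNI cells (-0.345 in cohort 1 and -0.273 in cohort 2; exact permutation p = 0.00804, adjusted p = 0.250). Macro1 made up 0.713% ± 0.227 of SI and 0.405% ± 0.310 of SNI cells (-0.258 in cohort 1 and -0.307 in cohort 2; exact permutation p = 0.0362, adjusted p = 0.394). Micro3, a subtype of microglia, stood at 1.12% ± 0.559 of SI and 0.645% ± 0.359 of SNI cells (-0.798 in cohort 1 and -0.201 in cohort 2; exact permutation p = 0.0121, adjusted p = 0.250). Among cOL, cOL2 stood at 0.455% ± 0.394 of SI and 0.155% ± 0.0997 of SNI cells (-0.161 in cohort 1 and -0.414 in cohort 2; exact permutation p = 0.0152, adjusted p = 0.250). Among Schwann cells nmSchwann1 stood at 0.747% ± 0.638 of SI and 0.161% ± 0.148 of SNI cells (-0.749 in cohort 1 and -0.389 in cohort 2; exact permutation p = 0.0205, adjusted p = 0.271). Inhib6 stood at 0.341% ± 0.239 of SI and 0.141% ± 0.146 of SNI cells (-0.222 in cohort 1 and -0.151 in cohort 2; exact permutation p = 0.0469, adjusted p = 0.394). Inhib8 stood at 0.217% ± 0.167 of SI and 0.403% ± 0.158 of SNI cells (0.226 in cohort 1 and 0.143 in cohort 2; exact permutation p = 0.0478, adjusted p = 0.394). None of the 66 subtypes passed in the exact permutation test after adjustment (8 at an unadjusted p under 0.05).

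UMIs of monocyte markers were 78.2 ± 24.6 CPM of all UMIs in SI and 56.4 ± 14.3 in SNI mice (exact permutation p = 0.0286, adjusted p = 0.283). Cspg4 stands in both the OPC and pericyte classes, and Vcan in the OPC and monocyte classes. Means in CPM of all UMIs in SI and SNI mice, with exact permutation p, were B cell 212 and 185 (p = 0.191), DRG neuron 122 and 115 (p = 0.847), Schwann cell 1626 and 1247 (p = 0.725), T cell or NK cell 8.52 and 6.89 (p = 0.650) and astrocyte 489 and 478 (p = 0.724). They were committed oligodendrocyte precursor 459.5 and 474 (p = 0.580), endothelial 3977 and 3617 (p = 0.321), ependymal 126 and 116 (p = 0.779), erythroid 151 and 355 (p = 0.477) and microglia 1274 and 1314 (p = 0.806). For the other classes they were neuron 2236 and 1981 (p = 0.339), neutrophil 22.5 and 74.3 (p = 0.483), oligodendrocyte 71789.6 and 78060.0 (p = 0.175), satellite glia 57554 and 62101 (p = 0.282) and smooth muscle 614 and 436 (p = 0.129). None of the 20 classes passed after adjustment. Leaving out single mice for these means was chosen after they were seen. The neutrophil value was 575 in SNI mouse 8, without which the SNI mean was 11.7, below the SI mean of 22.5. It was 199 in SI mouse 4, without which the SI mean was 2.96. The erythroid value was 2109 in SNI mouse 3, without which the SNI mean was 136, below SI. That of Schwann cells was 5911 in SI mouse 3, without which the SI mean was 1150.1, below SNI. The direction turned without 1 mouse for these 3 classes and for DRG neuron, T cell or NK cell, astrocyte, ependymal, fibroblast and microglia.

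Median log2 differences of lists that were not called by limma's camera were interferon response in Endothelial 0.068 (adjusted p = 0.557), mylOligo 0.039 (adjusted p = 0.333) and Oligo 0.053 (adjusted p = 0.589), and endothelial activation in Endothelial -0.027 (adjusted p = 0.826). There were also mitochondrial transcripts in Endothelial -0.017 (adjusted p = 0.830), Excit -0.079 (adjusted p = 0.248), Inhib -0.062 (adjusted p = 0.935), Micro -0.010 (adjusted p = 0.515), mylOligo 0.034 (adjusted p = 0.817) and Oligo 0.058 (adjusted p = 0.610), and immediate early and handling in Endothelial -0.046 (adjusted p = 0.866), Inhib -0.19 (adjusted p = 0.379) and Micro 0.023 (adjusted p = 0.539). Others were excitatory transmission in Excit -0.093 (adjusted p = 0.165), and inhibitory transmission in Excit 0.15 (adjusted p = 0.332). Further values were dorsal horn neuropeptides and receptors in Excit 0.014 (adjusted p = 0.810) and Inhib 0.14 (adjusted p = 0.557), and axon injury response in Excit -0.094 (adjusted p = 0.935) and Inhib 0.097 (adjusted p = 0.421). Next came integrated stress response in Inhib -0.019 (adjusted p = 0.646), mylOligo 0.090 (adjusted p = 0.653) and Oligo -0.043 (adjusted p = 0.935), and extracellular matrix in Leptomeningeal -0.19 (adjusted p = 0.245). The remaining list was cholesterol synthesis in mylOligo -0.060 (adjusted p = 0.382) and Oligo 0.086 (adjusted p = 0.163). Cell division in microglia, OPC and Endothelial had fewer than 5 tested members, as had interferon response in microglia, antigen presentation in Oligo and mylOligo, integrated stress response in Excit and immediate early and handling in OPC. The reactive astrocyte and astrocyte homeostasis lists, and complement, chemokines, interferon, cholesterol synthesis, mitochondrial, oxidative phosphorylation and handling lists in Astrocytes and extracellular matrix in Pericyte, were in types with too few cells to test.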
